A study of Mus musculus with 8 samples.

How the data were processed

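Total RNA of frozen hearts was labelled with biotin by the standard Affymetrix protocol, per the labels' protocols. The authors deposited log2 values of 41345 probe sets for 8 arrays. RMA, which corrects background, normalizes by quantiles and summarises probes, and limma are named without versions, per the submitters' processing notes. The array's genome build, its probe positions, hybridisation dates and array batches are not given in the sources used here, so no coordinates are printed and no batch could be tested. Quantile normalization makes the arrays' distributions alike, so a shift of all genes together would not be visible. Differences among the highest signals can be compressed, which was not measured.

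Samples were grouped by the genotype in the labels, 4 floxed control and 4 knockout hearts. No 2 arrays were identical, as was checked by their correlations (at most 0.988). The platform annotation gave 1 gene symbol for 23521 probe sets, several for 1814 and none for 16010, which stay unnamed here. Of those with 1 symbol, 23328 matched the RefSeq gene table by Entrez identifier and took its symbol, and 193 kept the symbol as given. Probe sets with several symbols or none were tested separately and gave 0 calls among 8934 with limma (556 at an unadjusted p under 0.05). For a gene with more than 1 probe set (1082 genes) the probe set with the highest mean over all arrays was used, which gave 22180 genes. A gene was tested when that mean reached the 40th percentile of all probe set means, 3.80 (log2), which left 15086.

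The comparison was knockout minus control with limma (lmFit and eBayes, no trend, not robust) in R 4.3.3 with limma 3.58.1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of differences are limma's standard errors from moderated variances. Single values were also tested by an exact two-sided permutation test over the 70 assignments, whose smallest p is 0.0286. The design, the gene lists, the naming rule and the alternatives other than the joint removal of knockout replicates 1 and 4 were chosen before the data were examined. There were 53 gene lists of pathways and cell type markers, of which 52 had at least 5 measured genes. The list of X-inactivation and Y-linked genes had fewer and was not tested. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, camera on ranks and fry, and Reactome mouse sets of 10 to 300 genes from fgsea 1.28.0 were tested likewise. Camera with the preset correlation was tested on simulated data of 51 lists that shared a common factor and no shift: it called 33, and the estimated correlation called 0. The estimated correlation was not tested on simulated lists with a shift, so its power with 4 against 4 arrays is not known. In the real data it was 0.80 for the collagen and matrix list and 0.70 for the fatty acid list. Over the lists called with the preset it ran from 0.01 (p53 targets) to 0.81 (activated fibroblast markers). The simulated 33 of 51 need not hold for lists with low values. A list score is the mean deviation of its genes from their means over the 8 arrays. The exact test of a list used standardised values.

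Named genes were a fixed panel of 17, then up to 10 genes per direction past the threshold without overlap between the groups, which gave 0 genes, then the 10 per direction with the smallest p and an absolute log2 difference of at least 0.4, and up to 4 members per list described with the smallest p in the list's direction. Genes outside this rule are said to be named after their values were seen.

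On simulated data with 4 against 4 arrays and the 15086 genes, the limma step recovered 74% of 100 genes changed by 0.5 (log2) and 97% of 100 changed by 1, with 11 false calls. The simulated genes varied independently, with moderated variances and no factor shared between genes. These shares therefore do not give the power on the real arrays, and 0 calls there cannot be read as absence of change. The alternatives were no filter, a filter at the 60th percentile, quantile normalization or a common median, the mean of a gene's probe sets, a trend with robust estimation, array weights, the replicate number as a block, the first principal component of the residuals as a covariate, an unmoderated test, an adjusted p of 0.1, and leaving out each array. Without knockout replicates 1 and 4 together was added after seeing the data. Those arrays had the highest matrix and activated fibroblast scores and the lowest fatty acid scores of all arrays. Smaller shifts of these lists without them therefore follow from the choice and do not test its cause. Calls can also be lost there because fewer knockout arrays remain.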

Results

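Gene expression was measured on Affymetrix arrays in hearts of male C57Bl6N mice 1 week after transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. The 8 arrays fell into 2 groups of 4, hearts with a knockout of CITED4 and floxed control hearts, in which the targeted allele carries recombination sites. Neither the Cre driver nor whether the controls carried Cre is given in the sources used here, so a difference between the groups can include an effect of Cre, and cells without deletion can add to the Cited4 signal. CITED4 is a transcriptional co-regulator that binds CBP/p300 and TFAP2 factors. All hearts had undergone TAC, so the design compared the 2 genotypes under pressure load and held no unoperated heart. Array medians lay between 4.29 and 4.33 (log2), and the correlation over probe sets between arrays ran from 0.979 to 0.988. The number of arrays limits the precision of every value below. The labels name hearts and number the samples, but do not state how animals, litters or array runs were assigned, so p-values measure the spread between these samples.

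Cited4 itself was lower in each knockout heart than in each control heart. Its signal (Entrez gene 56222) was 5.98 ± 0.20 in control hearts and 5.07 ± 0.19 in knockout hearts (log2 intensity, mean ± SD, n = 4 per group). The difference was -0.91 ± 0.12 (log2, SE; 95% interval -1.19 to -0.64), which left 53.1% of the control signal. Control values ran from 5.76 to 6.22 and knockout values from 4.83 to 5.26. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow. In the limma test over all genes Cited4 had the smallest p of the 15086 genes (2.19e-05), with an adjusted p of 0.277. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal cannot be read as remaining transcript.

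The knockout hearts had higher average signals for collagen, matrix and activated fibroblast genes and for several load-responsive genes, and lower signals for genes of fatty acid oxidation and mitochondrial respiration. The size of these shifts differed from heart to heart, and knockout replicates 1 and 4 lay farthest from the controls. No single gene passed the test: limma called 0 genes higher and 0 lower at an adjusted p of 0.05, and 0 at 0.1. At an unadjusted p under 0.05 there were 851 genes higher and 846 lower, 1697 in all where chance gives about 754 on average. Genes vary together across these arrays, so a chance count can lie far from that average. At an unadjusted p under 0.01 there were 321 genes. Of the 35 distinct splits of the 8 arrays 3 gave as many, the real one included (highest other 1050). The others were the real split with control replicate 1 exchanged for knockout replicate 3 (1050) or for knockout replicate 2 (537). They keep most of the genotype contrast, so they are not unrelated groupings. The excess does not set the genotypes apart from these groupings of the arrays, and chance is not excluded. A gene-by-gene test without moderated variances also called 0 after adjustment and had 1327 genes at an unadjusted p under 0.05. The 4 knockout values did not overlap the 4 control values in 789 genes (352 higher, 437 lower), 5.23% of those tested where chance gives 2.86% on average. This share was not counted over the other splits, so it cannot be read as an excess beyond chance. A log2 difference of at least 1 was seen in 26 genes higher and 2 lower in the knockout.

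Among markers of cardiac load, the skeletal alpha-actin gene Acta1, re-expressed in hypertrophy, was at 8.88 ± 0.23 in control and 9.37 ± 0.27 in knockout hearts (SD, n = 4), a difference of 0.49 ± 0.15 (SE) with no overlap between the groups. Myh7, the slow myosin heavy chain of the fetal ventricle, differed by 0.35 ± 0.16, and Myh6, the adult fast isoform, by -0.35 ± 0.13. Atp2a2, which encodes the sarcoplasmic reticulum calcium pump, differed by -0.21 ± 0.09, with no overlap between the groups. The natriuretic peptide genes differed little: Nppa by 0.09 ± 0.07, also with no overlap, and Nppb by 0.03 ± 0.09, at mean control signals of 13.21 and 11.99. That of Nppa lies near the highest signal on these arrays (13.3), where differences can be compressed. Nppb, Myh6, Myh7 and Atp2a2 also lay above the 99th percentile of gene signals (10.73). None of these passed, with adjusted p-values from 0.421 to 0.928. As a list, the 25 measured haemodynamic stress and fetal genes were called higher in the knockout with camera at a preset correlation of 0.01 (23 higher, 2 lower, median 0.26, adjusted p = 2.77e-06). The list had an adjusted p = 0.438 with an estimated correlation. No member passed over all genes, and 0 did adjusted over the list alone, with 9 at an unadjusted p under 0.05. Its Myl4 value in knockout hearts (difference 0.39 ± 0.14) included knockout replicate 2, an array with high atrial markers, and was 0.23 without that array.

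**Figure D1:**
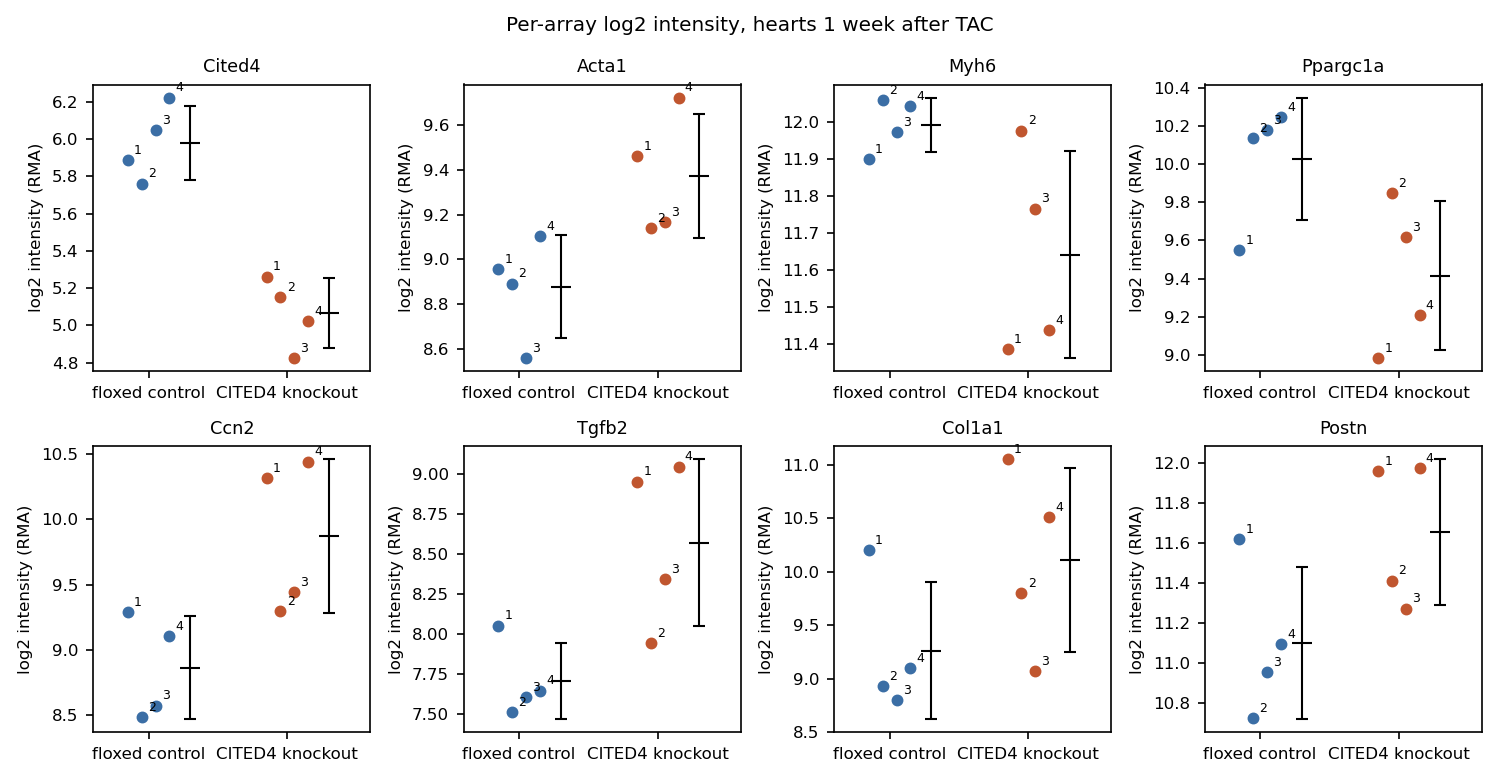
Log2 intensity (RMA, y axis) of 8 genes in floxed control and CITED4 knockout hearts 1 week after TAC. Points are single arrays numbered by replicate, and bars show the mean and SD of 4 arrays. Cited4 and Acta1 do not overlap between the groups, whereas for Col1a1 and Postn control replicate 1 lies among the knockout values.

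Fibrillar collagens and other matrix genes were higher on average in the knockout. Of 46 measured genes of the collagen and matrix list, 44 were higher and 2 lower, with a median difference of 0.59. Mfap4 differed by 0.71 ± 0.18, Mfap5, a microfibril component, by 0.43 ± 0.12, Pcolce, which enhances procollagen processing, by 0.43 ± 0.12 and Col5a1 by 0.59 ± 0.18. The structural collagen genes had wide spreads, with Col1a1 at 9.26 ± 0.64 in control and 10.11 ± 0.86 in knockout hearts (SD; difference 0.85 ± 0.42, SE, and 0.53 without knockout replicate 1) and Col3a1 at a difference of 0.62 ± 0.26. Postn, a marker of activated fibroblasts, differed by 0.56 ± 0.21 and Timp1, an inhibitor of matrix metalloproteinases, by 0.71 ± 0.27. Camera with the preset correlation called the list higher (adjusted p = 1.59e-16), with an adjusted p = 0.438 with an estimated correlation. The exact permutation test of the mean standardised value gave p = 0.114. No gene passed over all genes, 0 passed adjusted over the list alone, and 27 had an unadjusted p under 0.05. Without knockout replicates 1 and 4, an alternative chosen after seeing the data, the median was 0.20.

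Activated fibroblast and myofibroblast markers had the widest shift of the lists. The median difference of the 19 measured genes was 1.07, with 18 higher and 1 lower. Over all genes 0 passed, and adjusted over the list alone 2 did, Mfap4 and the transcription factor gene Meox1 (0.63 ± 0.16), with 13 at an unadjusted p under 0.05. Lox, the collagen cross-linking enzyme gene, differed by 1.5 ± 0.52 and Ccn4 by 1.27 ± 0.44. The list was called higher (adjusted p = 2.39e-09), with an adjusted p = 0.438 with an estimated correlation, and it shares 11 genes with the matrix list. Its median was 0.31 without knockout replicates 1 and 4. General fibroblast markers, 13 of 20 higher with a median of 0.09, missed the threshold with preset camera (adjusted p = 0.0587). With an estimated correlation they had an adjusted p = 0.538. They were called higher with preset camera without knockout replicates 1 and 4 (median 0.11, adjusted p = 0.0218).

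TGF-beta ligands and targets, a pathway that drives fibroblast activation, were called higher as well. Of 23 measured genes 19 were higher and 4 lower, with a median of 0.24. The ligand gene Tgfb2 differed by 0.87 ± 0.23, the matricellular genes Ccn2 by 1.01 ± 0.28 and Ccn1 by 0.85 ± 0.23, and Inhba, which encodes an activin subunit, by 0.76 ± 0.23. These 4 genes passed adjusted over the list alone, against 0 over all genes, and at an unadjusted p under 0.05 there were 8 members higher and 1 lower. Camera gave an adjusted p = 2.09e-05 with the preset correlation and an adjusted p = 0.438 with an estimated correlation. Its median without knockout replicates 1 and 4 was 0.10 and the call was lost (adjusted p = 0.149).

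**Figure D2:**
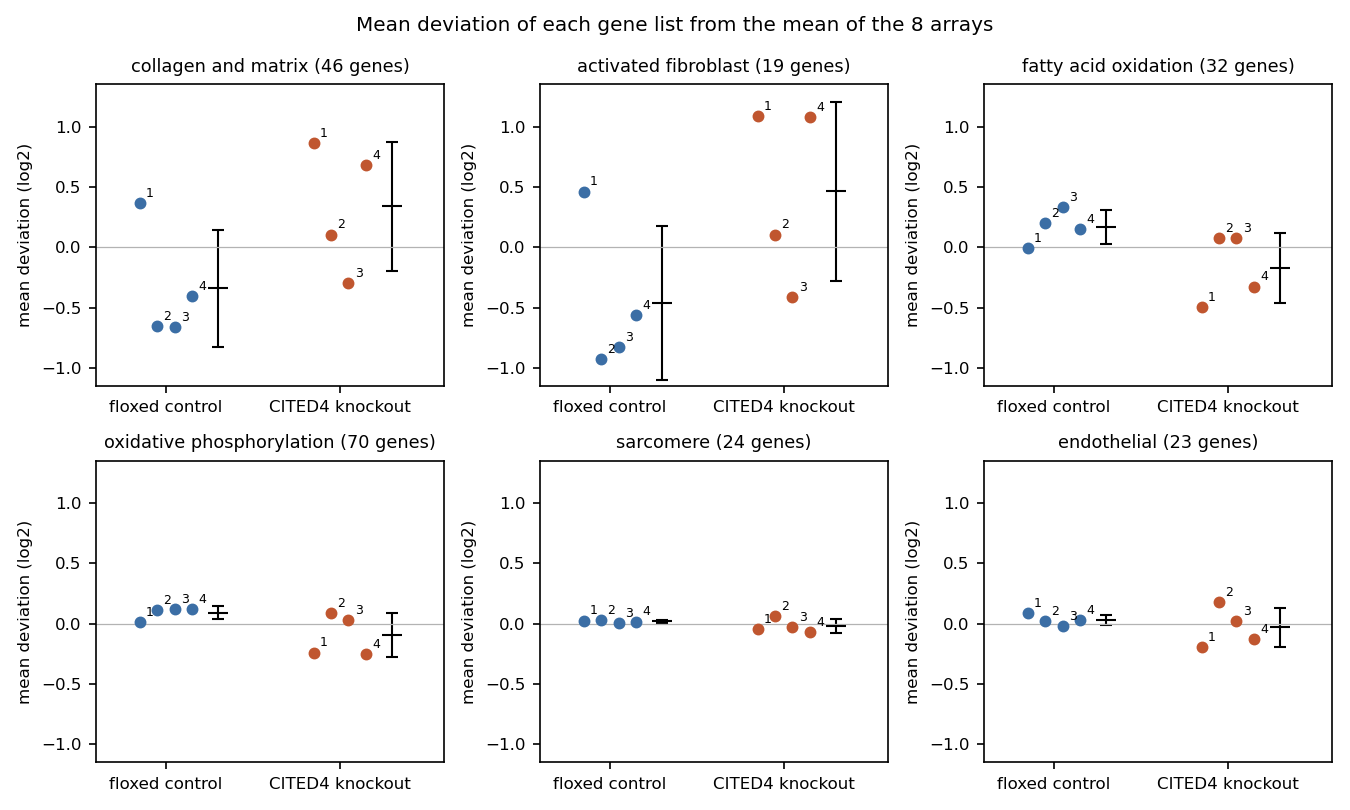
Mean log2 deviation of 6 gene lists from the mean of the 8 arrays (y axis), for floxed control and CITED4 knockout hearts. Points are single arrays numbered by replicate, with the mean and SD of 4 arrays beside them, and matrix and activated fibroblast scores were highest in knockout replicates 1 and 4 and, among controls, in replicate 1.

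Genes of fatty acid use and mitochondrial respiration were lower on average in the knockout. Of 32 measured genes of fatty acid uptake and oxidation, 31 were lower and 1 higher, with a median of -0.34. Cpt2, of the carnitine shuttle, differed by -0.46 ± 0.14, Acaa2, which encodes the thiolase of beta-oxidation, by -0.39 ± 0.12, and Etfa, which passes electrons to the respiratory chain, by -0.41 ± 0.14. For nuclear genes of oxidative phosphorylation 66 of 70 were lower, with a median of -0.19, among them Cox7a1 (-0.41 ± 0.14) and Ndufb10 (-0.36 ± 0.12). In the citric acid cycle and branched-chain amino acid list 30 of 33 were lower (median -0.20), among them Ppm1k, the phosphatase that activates branched-chain keto acid oxidation (-0.42 ± 0.15). Preset camera called these lists lower, with adjusted p-values of 2.99e-13, 6.1e-15 and 8.72e-10. The same lists had an adjusted p = 0.438, 0.446 and 0.438 with an estimated correlation, and each had an exact permutation p of 0.0857. No member passed over all genes or adjusted over the list alone (0 in each), and 17, 20 and 10 members had an unadjusted p under 0.05. The medians without knockout replicates 1 and 4 were -0.09, -0.05 and -0.07.

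Regulators of mitochondrial biogenesis were lower for 19 of 19 genes (median -0.22). Ppargc1a, the co-activator PGC-1 alpha, was at 10.03 ± 0.32 in control and 9.41 ± 0.39 in knockout hearts (SD), a difference of -0.61 ± 0.21 (SE). Mfn1, a mitochondrial fusion gene, differed by -0.32 ± 0.09 and Tfb2m, a mitochondrial transcription factor gene, by -0.34 ± 0.10. The list was called lower (adjusted p = 4.48e-09), with an adjusted p = 0.438 with an estimated correlation and an exact permutation p of 0.0286. It had 0 members past the threshold over all genes and 0 adjusted over the list alone, with 11 at an unadjusted p under 0.05. Across the 8 arrays the matrix and fatty acid scores were inversely related (Pearson r = -0.94, exact permutation p = 4.96e-05, adjusted p = 1.49e-04; Spearman rho = -0.98, exact permutation p = 3.97e-04). Without knockout replicates 1 and 4, the arrays farthest from the median matrix score, r was -0.87. After removal of each group's mean r was -0.90 (exact permutation p = 0.0104, adjusted p = 0.0312). It was 1 of 3 relations computed, which were chosen after the data were examined. Matrix against oxidative phosphorylation gave r = -0.88 (exact permutation p = 2.6e-03, adjusted p = 3.91e-03; rho = -0.93, exact permutation p = 2.23e-03; r = -0.72 without the same arrays; within groups r = -0.81, exact permutation p = 0.0365, adjusted p = 0.0547), whereas matrix against cell cycle gave r = 0.34 (exact permutation p = 0.403, adjusted p = 0.403; rho = 0.45, exact permutation p = 0.267; r = 0.70 without the same arrays; within groups r = -0.03, exact permutation p = 0.922, adjusted p = 0.922).

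**Figure D3:**
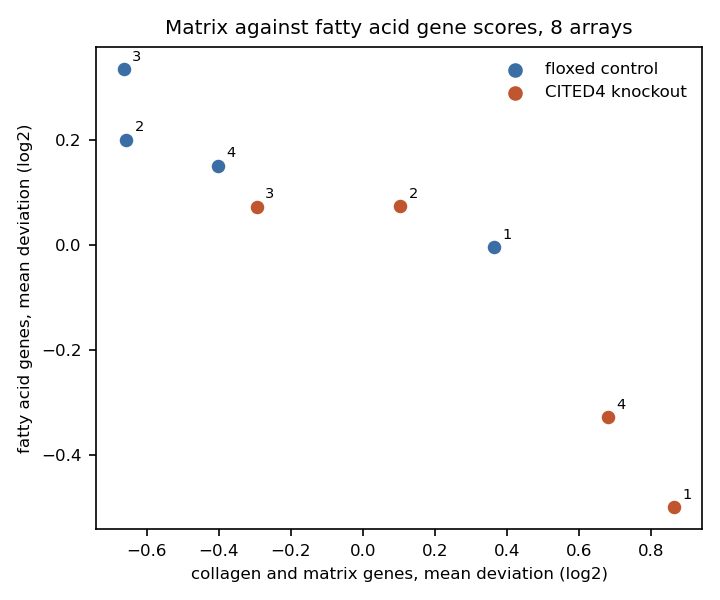
Mean deviation of fatty acid genes (log2, y axis) against that of collagen and matrix genes (log2, x axis) in 8 hearts, coloured by genotype and numbered by replicate. The scores are inversely related (r = -0.94), with knockout replicates 1 and 4 at 0.87 and 0.68 on the matrix axis and control replicate 1 at 0.36.

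Markers of the ventricular cardiomyocyte and cardiac ion channel genes were lower on average in the knockout. Of 18 measured ventricular markers 14 were lower (median -0.22), and Mpped2 (-0.39 ± 0.09) passed adjusted over the list alone, against 0 genes over all genes. Kcnd2 (-0.47 ± 0.13) and Kcnip2 (-0.67 ± 0.22), which form the transient outward potassium current, were among 15 of 17 ion channel genes that were lower (median -0.09). Of the ventricular markers 8 had an unadjusted p under 0.05. For the ion channel list 0 members passed adjusted over the list alone and 0 over all genes, with 6 at an unadjusted p under 0.05. Preset camera called both lists lower (adjusted p = 3.44e-04 and 1.22e-03), and both had an adjusted p = 0.438 with an estimated correlation. Both calls were lost without knockout replicates 1 and 4, where the ventricular median was -0.04 (adjusted p = 0.105) and that of the ion channels -0.08 (adjusted p = 0.255). The ventricular median was -0.14 without knockout replicate 1, and that of the ion channels was -0.21, -0.15, -0.16 and -0.16 without knockout replicate 2, knockout replicate 3, control replicate 1 and control replicate 3. It was -0.25 with the filter at the 60th percentile and -0.15 with no filter. Sarcomere genes were not called (16 of 24 lower, median -0.03, adjusted p = 0.21), and 13 of these 24 lay above the 99th percentile of gene signals.

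Cell cycle genes were higher in 41 of 48 cases, with a median of 0.15. Tpx2, a spindle assembly factor gene, differed by 0.37 ± 0.10 and Ccnb2, which encodes cyclin B2, by 0.30 ± 0.08, each with no overlap between the groups. The list was called higher (adjusted p = 4.4e-07), with an adjusted p = 0.446 with an estimated correlation. Over all genes 0 members passed, adjusted over the list alone 0 did, and 11 had an unadjusted p under 0.05. Its median was larger, 0.25, without knockout replicates 1 and 4. Their cell cycle scores (-0.04 and 0.01) were the lowest of the knockout hearts, so this rise follows from which arrays were removed. For p53 targets 18 of 24 were higher (median 0.16), Phlda3 by 0.45 ± 0.11. This list was called higher (adjusted p = 0.0137), with an adjusted p = 0.438 with an estimated correlation. That estimate was 0.01, near the preset value, and camera's unadjusted p was 4.21e-03 with the preset and 0.0299 with the estimate. The p53 list lost the call without knockout replicates 1 and 4 (median 0.06, adjusted p = 0.14). With the filter at the 60th percentile it was also lost (median 0.11, adjusted p = 0.0832).

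Immune and inflammatory genes were called higher by smaller amounts. Of 29 interferon response genes 23 were higher (median 0.15), with Bst2 at 0.61 ± 0.15, and of 16 complement and acute phase genes 14 were higher (median 0.15), with C1ra at 0.40 ± 0.12. Macrophage and monocyte markers were higher in 20 of 27 cases (median 0.17), and cytokines and chemokines in 20 of 29 (median 0.10), with Cx3cl1 at 0.58 ± 0.16. For immediate early genes 20 of 26 were higher (median 0.14), with Ier3 at 0.53 ± 0.17, and for cytosolic ribosomal proteins 35 of 46 (median 0.08). The preset adjusted p-values were 1.22e-03 for interferon response, 2.39e-03 for complement, 0.0166 for macrophages, 0.0376 for cytokines, 3.33e-03 for immediate early genes and 0.0129 for ribosomal proteins. In the same order these lists had adjusted p = 0.503, 0.438, 0.503, 0.438, 0.446 and 0.561 with an estimated correlation. In each of these and the p53 list 0 members passed over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 5 interferon, 6 complement, 2 macrophage, 6 cytokine, 4 immediate early and 6 ribosomal genes, all higher, and among p53 targets 4 higher and 1 lower. Single arrays decided several of these calls. The interferon call was lost without knockout replicate 2 (median 0.11, adjusted p = 0.0649) or control replicate 3 (median 0.09, adjusted p = 0.0928). The macrophage call was lost without knockout replicate 1 (median 0.10, adjusted p = 0.0895), knockout replicate 3 (0.15, 0.382) or control replicate 3 (0.12, 0.0928). The cytokine call was lost without knockout replicate 3 (median 0.08, adjusted p = 0.211), knockout replicate 4 (0.08, 0.0749), control replicate 2 (0.04, 0.0814) or control replicate 3 (0.06, 0.189). That of immediate early genes was lost without knockout replicate 4 (median 0.10, adjusted p = 0.063), and its median was 0.09 without control replicate 1. The ribosomal call was lost without knockout replicate 1 (median 0.05, adjusted p = 0.213) or control replicate 2 (0.07, 0.0755). Without knockout replicates 1 and 4 together, the ribosomal (median 0.06, adjusted p = 0.186) and immediate early calls (0.08, 0.0784) were also lost, and with camera on ranks that of cytokines (adjusted p = 0.0666).

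In all, preset camera called 12 of 52 lists higher and 6 lower. With an estimated correlation camera called 0 of the 52 (3 at an unadjusted p under 0.05), and fry, which tests whether a list's genes move on balance one way, called 0 (9 at an unadjusted p under 0.05). An exact permutation test of each list's mean had 5 lists at p = 0.0286, with a smallest adjusted p of 0.248. That is the smallest p that 4 against 4 arrays allow. Over 52 lists no adjusted p could pass unless many lists reached it, so this test could hardly call any. Among the 34 lists not called, adjusted p-values ran from 0.0587 to 0.706. These included endothelial markers (median -0.03, adjusted p = 0.131), hypoxia targets (0.01, adjusted p = 0.467), the mTORC1 and ATF4 response (-0.04, adjusted p = 0.329), and genes next to Cited4 (0.08, adjusted p = 0.48). Circadian genes (median 0.05, adjusted p = 0.467) were called higher without knockout replicates 1 and 4 (median 0.17, adjusted p = 6.87e-03). Pericyte and smooth muscle markers had a median of -0.08 and a mean of 0.05 with a test direction of lower. Adipocyte markers had a median of 0.04 and a mean of 0.02 with a test direction of lower. For glycolysis the median was -0.0024, the mean 0.0078 and the test direction lower.

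Atrial cardiomyocyte markers stood apart in knockout replicate 2. Sln, which encodes the atrial calcium pump inhibitor sarcolipin, was at 9.31 on that array and between 2.75 and 4.98 on the other 7. Myl7, the atrial light chain gene, was at 9.02 against 4.03 to 5.04. Both were named after their values were seen. Of the 16 measured markers 7 were highest on that array, with a median excess of 0.42 over the mean of the other arrays, whereas Nppa (0.05), Stk39 (-0.04) and Myl1 (-0.39) were not. Stk39 and Myl1 were likewise named after their values were seen. The list was not called between the genotypes (median 0.10, adjusted p = 0.143), but was called higher without knockout replicates 1 and 4 (median 0.11, adjusted p = 0.0153), where knockout replicate 2 was 1 of 2 knockout arrays.

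The Cited4-related genes Cited2 (0.12 ± 0.14) and Cebpb (0.02 ± 0.13), and the probe set of the microRNA gene Mir30d (-0.04 ± 0.14), differed by less than their errors. Among genes with the smallest p and a difference of at least 0.4, Hbegf, which encodes a growth factor of cardiac hypertrophy, differed by 0.92 ± 0.18. Clca3a1 differed by 0.79 ± 0.12, Atp6v0a4 by 0.74 ± 0.14, Epn3 by 0.64 ± 0.10, Tox3 by 0.50 ± 0.09, Ckap2l by 0.48 ± 0.08, Gm10865 by 0.45 ± 0.07, 4930563E22Rik by 0.42 ± 0.08, Atoh8 by 0.41 ± 0.09 and Pard6b by 0.40 ± 0.07. The control means of Clca3a1 (3.50) and Atp6v0a4 (3.76) and the knockout mean of Slc2a12 (3.79) lay under the filter value of 3.80, so the sizes of these differences are uncertain. In the other direction the glucose transporter gene Slc2a12 differed by -0.65 ± 0.11, the sodium-proton exchanger gene Slc9a2 by -0.57 ± 0.09 and Abcd2, a peroxisomal fatty acid transporter gene, by -0.54 ± 0.11. Gm9292 differed by -0.68 ± 0.14, 4921504A21Rik by -0.62 ± 0.12, Vwa3a by -0.55 ± 0.10, Gpr157 by -0.54 ± 0.12, Olfr700 by -0.42 ± 0.09 and Abhd3 by -0.40 ± 0.09. None of these passed, with adjusted p-values from 0.277 to 0.421 for the genes with the smallest p and from 0.767 to 0.956 for Cited2, Cebpb and Mir30d.

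Named after its values were seen, Sprr1a, a stress-induced gene of the cornified envelope family, had the largest difference of all genes tested. It was at 6.05 ± 2.42 in control and 9.60 ± 1.97 in knockout hearts (SD), a difference of 3.55 ± 1.21 (SE). An exact two-sided permutation test gave p = 0.0857 and limma an adjusted p of 0.421. Control replicate 1, at 9.35, lay above knockout replicates 2 and 3, at 8.93 and 7.13.

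In a principal component analysis of the 8 arrays, likewise not part of the fixed design, the first component took 43.5% of the variance. Knockout replicates 1 and 4 scored -28.1 and -19.8, knockout replicates 2 and 3 scored 1.28 and 5.85, control replicate 1 scored -4.15 and the other controls between 11.9 and 17.0. Knockout minus control was -20.4 on it, with SDs of 16.3 in knockout and 9.80 in control hearts. An exact two-sided permutation test did not decide whether the groups differ (p = 0.0857).

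A screen of 797 Reactome sets with preset camera called 33 higher and 15 lower. With an estimated correlation it called 0 (6 at an unadjusted p under 0.05), and fry called 0 (59 at an unadjusted p under 0.05). The lower sets included respiratory electron transport (65 of 69 genes lower, median -0.17) and mitochondrial translation (72 of 79 lower, median -0.13). The higher sets included elastic fibre formation (28 of 34 higher, median 0.39) and collagen formation (51 of 63 higher, median 0.19). Each of these sets had an adjusted p = 0.929 with an estimated correlation. The screen without knockout replicates 1 and 4 called 12 higher and 0 lower, with 15 lower sets at an unadjusted p under 0.05.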

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

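The tests of single explanations in this part were chosen after the patterns were seen, apart from the counts over other splits of the arrays. For lists and sets, counting those splits in either direction was added after the counts were seen. The further atrial genes were fixed before their own values were seen.

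Matrix genes were higher and fatty acid genes lower on average in the knockout, and the weighing could not place the difference in the genotype alone. Deviations of knockout replicates 1 and 4 from the mean of the other 6 arrays correlated at 0.667 (the highest of 28 pairs of arrays, the next at 0.597). In 1000 simulated pairs with noise independent from gene to gene the highest was 0.203. Another pair also passed that bound, and these 2 arrays were singled out because their genes had shifted alike. The test therefore restates the pattern and decides nothing about its cause. A technical factor shared by many genes on an array stays open. Whether knockout replicates 1 and 4 carry the whole difference cannot be told apart, since the matrix score difference was 0.24 (SE 0.31) without them and 0.68 with all arrays. A lower share of cardiomyocytes with all other cell types gaining alike was argued against as the whole cause by the slope of the endothelial on the activated fibroblast score (-0.0706, 95% interval -0.25 to 0.11), while the gaps between the genotypes alone did not decide: 0.99 for activated fibroblast minus endothelial markers (SE 0.53, exact permutation p = 0.143) and -0.30 for fatty acid minus sarcomere genes (SE 0.15, exact permutation p = 0.114). The fatty acid minus sarcomere gap, for which that explanation stays open, is 2.06 standard errors, past the bound of 2 first written for that test, and the requirement of an exact p under 0.05 was added after these values were seen.

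Atrial markers stood apart in knockout replicate 2. The score of the atrial cardiomyocyte list was 0.929 on that array and between -0.20 and -0.08 on the other knockout arrays, and of the 16 measured markers 7 were highest there. Atrial tissue in that sample is a candidate explanation: of 6 further atrial genes the 4 measured lay above the mean of the other arrays by a median of 0.34, and no other array exceeded 0.13. Of these Kcnj5 and Stard10 were highest on that array, whereas Pam (10.88, with 11.11 on another array) and Sbk2 (4.98, with 5.01 on another) were not. The test of an array-wide fault did not decide, because the ventricular score of 0.0856 lay outside the -0.26 to 0.00 of the other knockout arrays but within the 0.05 to 0.12 of the controls, which were added to the test after the value was seen; the array's median correlation with the others (0.983) lay among theirs (0.982 to 0.986). The label names the heart, of which the atria are a part.

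Control replicate 1 lay toward the knockout arrays in matrix genes, with a matrix score of 0.36 where the other controls lay between -0.66 and -0.40. A knockout heart under a control label was argued against, because Cited4 was 5.89 on that array, the highest knockout value was 5.26 and the control SD was 0.20. No biological explanation was tested.

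In groups of 4 a value was singled out when its gap to the nearest other took more than 0.83 of the group's range. This held in 11 of 178 groups (6.18%), where chance gives about 1 in 20, and 7 of the 11 were in control replicate 1. With only the called lists it held in 5 of 110 groups; the other lists were added after the atrial scores were seen. In control replicate 1 these were Ppargc1a (9.55 against 10.14 to 10.25 in the other controls) and the scores of oxidative phosphorylation (0.0151), citric acid cycle and branched-chain amino acids (-0.00864), ventricular markers (0.047), chondrocyte and osteogenic genes (0.234), calcium handling (0.113) and T and NK cell markers (4.01e-05). Elsewhere they were Tox3 in control replicate 3 (6.42), fibroblast markers in knockout replicate 3 (-0.0822), the atrial score of knockout replicate 2 and its calcium handling score (0.396 against -0.15 to -0.12 on the other knockout arrays). Both calcium handling scores rest largely on Sln, which is in the atrial list too. Without Sln that of knockout replicate 2 was 0.06 (others -0.10 to -0.06) and that of control replicate 1 was 0.0674 (others 0.0204 to 0.068), so they add little to the atrial pattern.

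Counted over splits in either direction, chance could not be excluded for any count of lists or sets between the genotypes. For genes the real count was 0 in both directions, so all 35 distinct splits of the 8 arrays reach it (35 for genes higher, 35 for genes lower) and the count decides nothing. The highest other split called 199 genes in one direction. It set control replicate 1 and knockout replicates 1, 2 and 4 against the rest, and points to a structure of the samples. A split and its mirror are the same split, so its lists called in either direction were compared with the real count. The test had been written for the same direction, and the change was made after the counts were seen. For lists called higher 2 of 35 splits, the real one included, reached the real 12 (5.71%, highest other 14), and for lists called lower 23 reached the real 6 (highest other 14). Counted by direction over the 70 assignments, 2 reached the 12 lists higher (2.86%), so for this count the verdict depends on the way of counting. In total 5 splits reached the real 18 lists (highest other 19). For Reactome sets 10 reached the real 33 higher and 18 the real 15 lower (highest other 115), in either direction. By direction 35 of 70 assignments reached the 6 lists lower, 10 the 33 sets higher and 22 the 15 sets lower.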

How the results depend on the processing

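The removal of knockout replicates 1 and 4 together was chosen after seeing the data, and the other alternatives before. Over 18 alternatives the Cited4 difference ran from -0.99 to -0.83, with adjusted p-values from 0.0134 to 0.988. Named genes were all uncalled in the main test. Of 630 values for them 596 kept their direction and stayed uncalled, 25 passed the threshold and 9 changed sign. All 25 passes came with the first residual principal component as a covariate, the only alternative that called genes. Of 378 values of called lists 322 kept direction and call, and 56 lost the call. With the first residual principal component as a covariate limma called 212 genes higher and 143 lower and Cited4 passed (-0.91, adjusted p = 0.0134). The test of Cited4 itself hardly changed (SE 0.121, against 0.123 in the main test), and its unadjusted p was not smaller. Its pass therefore came from the adjustment over all genes and is no added evidence for Cited4. SEs of other called genes shrank, such as Lox (0.11 against 0.52), but that of Slc9a2 stayed at 0.09. What the component stands for was not tested. With an estimated correlation camera called 0 lists higher and 0 lower, and 0 Reactome sets higher and 0 lower. With fry it was 0 lists higher, 0 lower, 0 Reactome sets higher and 0 lower; at an unadjusted p under 0.05 the 2 tests had 3 and 9 lists, and 6 and 59 Reactome sets. On the 6 arrays without knockout replicates 1 and 4, 12 Reactome sets were higher and 0 lower (15 lower at an unadjusted p under 0.05), and limma called 0 genes (617 at an unadjusted p under 0.05). Leaving out each array gave 10 to 15 lists higher and 6 to 10 lower (10 without knockout replicate 2), 22 to 54 Reactome sets higher (54 without control replicate 1) and 13 to 17 lower, and 0 genes. Signs changed for genes near 0, and the cause was not tested: Nppb ran from -0.0177 to 0.0841 over left-out arrays and was -0.0571 without knockout replicates 1 and 4, Cebpb was -0.0145 with array weights and -0.0618 to 0.132 over left-out arrays, Cited2 was -0.0574 without knockout replicates 1 and 4, and Mir30d ran from -0.12 to 0.11. With the replicate number as a replicate block, 16 lists were higher and 7 lower, and Cited4 had an adjusted p of 0.125. Residual correlations of arrays with equal numbers were 0.36, 0.01, 0.28 and -0.03, with a mean of 0.16 against -0.05 for unequal numbers. The array of equal number was the best partner of control replicates 1 and 3 but not of 2 and 4. So few values do not decide whether the numbers pair the arrays. Signal over background limits genes near 3.80 (log2), such as Mir30d at 4.31, Clca3a1 at 3.50 and Atp6v0a4 at 3.76 in controls, where differences can shrink.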

Other observations

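The tests across arrays in this part were chosen after the relation was seen, and after the comparisons of gaps between cell type lists had not decided; the residual component was planned.

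Some genes stood out within lists that were not called. The adjustment was made within each list and not over the 34 lists scanned, so some of these passes can arise by chance. Among circadian genes Bhlhe41 differed by 0.39 ± 0.09, Wee1 by 0.26 ± 0.08 and the activator gene Npas2 by -0.32 ± 0.09, each past the threshold adjusted over the list alone and not over all genes. The squalene epoxidase gene Sqle (0.36 ± 0.08), the podoplanin gene Pdpn (0.43 ± 0.11) and the skeletal calsequestrin gene Casq1 (0.50 ± 0.15) were higher on the same terms. The mitochondrial chaperonin gene Hspe1 (-0.38 ± 0.08) and the triglyceride lipase gene Pnpla2 (-0.28 ± 0.07) were lower. Npas2 and Hspe1 were named after their values were seen.

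In the Reactome screen, tubulin folding after the chaperonin step (13 of 15 higher, median 0.25) and kinesins (14 of 18 higher, median 0.17) were called higher with preset camera. Antigen presentation by MHC class II was called as well (56 of 70 higher, median 0.09). Each had an adjusted p = 0.929 with an estimated correlation.

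A graded state that varies between hearts within each genotype may underlie the inverse relation of matrix and fatty acid scores. After each group's mean was removed r was -0.90 (exact permutation p = 0.0104), but this largely restates the relation that prompted the hypothesis, and a varying share of cardiomyocytes would give the same sign. A lower share with all other cell types gaining alike was argued against as the whole cause, because the endothelial score did not follow the activated fibroblast score (slope -0.0706, 95% interval -0.25 to 0.11, group as covariate). A lower share through a gain of fibroblasts alone stays open, and ventricular markers go with it: 14 of 18 were lower in the knockout, with scores of -0.26 and -0.22 in knockout replicates 1 and 4. General fibroblast markers, which a gain of fibroblasts should raise, moved much less (median 0.09, 13 of 20 higher) than activated fibroblast markers (median 1.07).

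For the fatty acid genes a lower share of cardiomyocytes cannot be told apart from a change within them. The slope of the sarcomere score on the fatty acid score was 0.10 (-0.08 to 0.28), where a lower share needs about 1, but 13 of 24 sarcomere genes lay above the 99th percentile of gene signals (10.73), where differences can be compressed, which was not measured. The 11 sarcomere genes at or below that level had a slope of 0.0978 (-0.21 to 0.40), whereas 7 ventricular markers at or below it and in neither list had a slope of 0.41 (0.12 to 0.69). Cell counts in sections of the same hearts would test it.

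With the residual component as a covariate, 355 genes were called, and 97 of them had groups that did not overlap. Over the 35 splits 3 gave as many, the real one included, so chance could not be excluded. The others exchanged control replicate 1 for knockout replicate 3 (1120) or for knockout replicate 2 (490), and so keep most of the genotype contrast. In 20 simulated unchanged data sets, whose genes varied independently, there was at most 1 call.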
